A study of Danio rerio with 2 samples.

How the data were processed

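Zebrafish (Danio rerio) eggs received 10.3 ng per embryo of one of a pair of morpholinos, antisense oligonucleotides used to block gene function. The first blocks translation of the transcript of estrogen receptor beta2, written ers2a in the labels and taken here to be the gene now named esr2a; the second is a control morpholino. Embryos were fixed at 8 or 48 hours post fertilization (hpf), and total RNA was labelled and hybridised to Agilent 2-colour zebrafish arrays. Per the labels, Cy5 carried the RNA of MO2-ers2a embryos and Cy3 that of MO-control embryos on both arrays, and the channel names in the file headers agree. There was 1 array per time, with no dye swap and no replicate, so each value below rests on 1 hybridisation. No test between conditions was possible and no p-value is given. The number of embryos per RNA sample and whether the same clutch served both times are not given in the sources used here.

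Scanner values were deposited as intensity per spot: per the file headers, the median signal and the median background of each channel. Mean signals, outlier marks and well-above-background marks were not used here. The plan fixed before the data were examined named mean signals; the medians took their place. It also named Agilent's own log ratio as a fallback, and that reading would make the authors' values the main ones; the report gives the authors' counts beside its own for this reason. The deposited series matrix holds log10 values by spot number. Over 4004 bright spots at 8 hpf and 2862 at 48 hpf, these rose with the raw log2 Cy5/Cy3 ratio with slopes of 0.295 and 0.303 and Pearson r of 0.987 and 0.995, so they are log10 of Cy5 over Cy3 with the same direction. The column medians were 0 at both times, and 36.8% and 34.7% of spots stood at exactly 0, which were treated as not measured. The medians of the non-zero values were 0.0185 and 0.0157. Agilent Feature Extraction made the values, per the submitters' processing notes; its version and the authors' dye normalization are not given in the sources used here.

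The signals were corrected for background with limma 3.58.1 in R 4.3.3 (normexp, offset 50) and normalized within each array by loess, with control spots at weight 0. A log2 ratio above 0 means more signal in MO2-ers2a embryos. A spot counted as measured when both background-subtracted signals exceeded the mean plus 2.6 SD of 153 negative control spots. This rule was chosen after seeing the data. The limits were 24.4 (Cy5) and 59.9 (Cy3) at 8 hpf, and 27.7 and 70.1 at 48 hpf. Of the negative control spots, 0% at 8 hpf and 1.31% at 48 hpf passed in both channels. A gene's value is the median over its measured spots, since repeated spots of one probe cannot be told from different probes in these files. Cy5 signals reached 257330 at 8 hpf and 193230 at 48 hpf, each on 1 spot, with no pile-up at a top value, and bright spots were kept. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

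The arrays hold 43839 spots that are not controls. Array names were updated through an NCBI RefSeq gene table of assembly GRCz12tu and a table of Ensembl names, used for names only. A current symbol was assigned to 18999 spots, for 12611 symbols; 13392 of all spots were matched through an older symbol or a gene ID. Another 23172 spots found no match and keep the name of the array design, 138 had an ambiguous older symbol, and both kinds were counted but are not named. Some names of the design had been turned into calendar text by a spreadsheet, and these stayed unnamed.

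A gene was called higher or lower at 2-fold or more, and a difference between times was called at 4-fold. These are rules of size. The genes named are, per array, the 12 highest and 12 lowest with an assigned symbol that were also 2-fold in the authors' log ratio; the 2 highest and 2 lowest members of each of 28 gene lists; 6 each way by the difference between times; 6 each way that were 2-fold at both times; 4 each way measured in 1 channel; and the estrogen receptors. Rule and lists were fixed before the data were examined, and 1 further list fixed then is not reported here, for a reason unrelated to its values, and is in no count of lists; the text gives the members that its sentences need. Each list of at least 3 measured genes was given the percentile of its median log2 ratio among 10000 random lists of the same size, matched on mean intensity in 20 bins. The middle 95% runs from percentile 2.5 to 97.5, and the percentile describes these arrays only. For a gene measured in 1 channel only, a bound is given: the bright channel against the higher of the dim channel's own signal and the lowest measured signal, after loess and Aquantile. Where the dim channel's own signal is used, it was not above background and carries noise, so such a bound is not a strict limit. The bounds are also open to dye bias, as are all values here, since no dye swap was made. A gene-specific dye bias of the same size on both arrays would raise the correlation between them and cancel in their difference. That the size was the same is an assumption. The mean log2 ratios of spike-in probes changed by unequal amounts from 8 to 48 hpf: 2.90 to 2.51 for E1A_r60_a22, and -1.17 to -1.22 for E1A_r60_n11.

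The procedure was tested on simulated arrays with the real brightness and background, a known dye trend and 200 changed genes each. Changed genes were drawn only from those with a bright spot, so the shares called hold for such genes. Ratio noise per spot, apart from background noise, was set below the pooled SD between real spots of a gene, 0.32 at 8 hpf and 0.24 at 48 hpf. The counts of unchanged genes called depend on that setting and give no rate of false calls on the real arrays. In the simulation of the 8 hpf comparison, with 16330 genes, 32.8% of 2-fold, 98.5% of 3-fold and 100% of 6-fold genes were called at 2-fold, and 0 unchanged genes were. In that of the 48 hpf comparison, with 17001 genes, the shares were 23.9%, 100% and 100%, and 0 unchanged genes were called. A true 2-fold difference was returned at a median of 0.95 and 0.90 on the log2 scale, because the offset shrinks ratios. Of 200 random lists of 20 unchanged genes, 4.5% at 8 hpf and 8% at 48 hpf fell outside the middle 95%. The alternatives were the authors' values, centring without loess, no background correction, 3 other filters on dim spots, 2 other gene summaries and 2 other fold sizes; scaling on the E1A spike-in spots and centring on measured spots were chosen after seeing the data. Array number limits the precision of every value.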

Results

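Transcript levels were compared between zebrafish embryos injected with the MO2-ers2a morpholino and embryos injected with a control morpholino, at 8 hpf (gastrula) and 48 hpf (hatching period). Each time had 1 2-colour array, so no value below has a replicate error. Of 43839 spots, 19465 (44.4%) were above background in both channels at 8 hpf and 21008 (47.9%) at 48 hpf. These gave log2 ratios for 15356 genes and unnamed transcripts at 8 hpf (8292 with an assigned symbol) and 16630 at 48 hpf (9111 with one). The pooled SD between spots of the same gene was 0.32 at 8 hpf and 0.24 at 48 hpf on the log2 scale. Among the E1A spike-in probes, each printed 32 times, the SD between spots ran from 0.02 to 0.13, which is technical spread within an array.

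The targeted receptor transcript was too dim for a ratio. The 2 esr2a spots had mean signals, background included, of 102 in Cy5 and 85.2 in Cy3 at 8 hpf, and of 101.5 in Cy5 and 90.5 in Cy3 at 48 hpf. No esr1, esr2a or esr2b spot was above background in both channels on either array, and gper1 was not analysed here. A morpholino that blocks translation need not lower its target transcript, so these spots are no check of the labels. Of 10 estrogen-responsive genes, 1 was measured at 8 hpf, f13a1b at 2.35, and 2 at 48 hpf, f13a1b at -0.40 and vtg1, a yolk protein gene induced by estrogen in the adult liver, at -0.08. With fewer than 3 members measured, this list has no percentile.

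At 8 hpf, MO2-ers2a embryos had lower levels of interferon-response and maternal transcripts and higher levels of hox transcripts than other genes of like brightness. Single genes differed far more. tgm2b, a transglutaminase, was 39.4-fold lower, ggact.2 20.4-fold lower and quob 14.7-fold lower, while isca1, an iron-sulfur cluster assembly factor, was 16.4-fold higher and gnmt, a glycine methyltransferase, 13.3-fold higher. Each of these rests on 1 spot, and the authors' log2 ratios were larger: -6.34 for tgm2b, -6.74 for ggact.2, -4.38 for quob, 4.88 for isca1 and 5.48 for gnmt. Among the next lowest were s100a10b at -3.52 (2 spots, -3.73 and -3.30), the bile-salt and drug transporter gene abcc2 at -3.48, dhcr7, which acts in the last step of cholesterol synthesis, at -3.20 (2 spots, -3.27 and -3.12), the autophagy receptor sqstm1 at -3.19, and b2m, the light chain of MHC class I, at -2.97. Then came nap1l4a at -2.83, her13 at -2.59, dennd2b at -2.53 and chrna2a at -2.49. Among the next highest were the prefoldin subunit pfdn2 and cfap100, both at 3.07, arfgap1 at 3.05, tnfaip2a at 3.01, tspan34b at 2.74, the mTORC1 inhibitor ddit4 at 2.72, rdh12l at 2.69, fat3a at 2.63 and mal2 at 2.44. cyp11a1.1, which starts steroid synthesis from cholesterol, stood at 2.41, but its 3 spots ran from -0.46 to 4.36.

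In all, 356 genes and transcripts were at least 2-fold higher and 346 at least 2-fold lower at 8 hpf, of which 146 and 183 had an assigned symbol; 60 and 43 reached 4-fold. Of 82 such genes with 2 or more spots, 76 (92.7%) had all spots on the same side of 0 and 40 had all spots at 2-fold or more. The split depends on the scaling: the authors' log ratios gave 705 higher and 1030 lower, spike-in scaling 234 and 551, and centring on all spots without loess 2490 and 96. Spike-in scaling moved the median of all measured spots to -0.17 at 8 hpf and 0.08 at 48 hpf, and centring on all spots moved it to 0.57 and 0.39, so levels are given relative to the other genes of the array.

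The interferon list had all of its 11 measured members below 0 at 8 hpf, with a median of -0.51 (percentile 0.04). Of these, 3 were 2-fold lower: b2m, ifi27.1 at -1.48 and ifit8 at -1.23. With the authors' values the median was -1.21, 7 of the 11 were 2-fold lower (ifit8 at -3.32), and irf7 at 0.89 and stat1a at 0.85 lay above 0. Maternal and germ plasm transcripts, supplied by the egg, had a median of -0.24 (percentile 0.29), or 0.30 with centring on all spots. Of 33 measured, 25 lay below 0 and 2 were 2-fold lower, both RNA-binding protein genes of the germ line, rbpms2a at -1.37 and dazl at -1.10 (3 spots, -1.19 to -0.19), where the authors' values gave 5; the highest were ddx4 at 0.75 and zp3b at 0.34. Among the brighter spots alone, the list stood at percentile 3.51. The hox genes, which pattern the body axis from head to tail, had a median of 0.40 (percentile 100). Of 28 measured, 21 lay above 0 and 0 reached 2-fold; hoxc3a was at 0.89 and hoxd3a at 0.86, against hoxb13a at -0.96. With the authors' values the median was 0.67, 24 lay above 0, 3 were 2-fold higher, among them hoxd3a at 1.45, and 1 was 2-fold lower, hoxb13a at -3.03. The 77 ribosomal protein genes had a median of 0.14 (percentile 99.4), which was -0.02 under spike-in scaling, and 58 lay above 0. The list came inside the middle 95% with the authors' values (percentile 97.4) and among the brighter spots alone (96.8). Only rpl36 among them was 2-fold higher, at 2.05, and its 2 spots gave -0.01 and 4.11. That made 4 of the 25 lists with a percentile outside the middle 95% at 8 hpf. If genes varied independently, 1.25 would be expected, or 1.125 at the 4.5% found in the simulation for lists of unchanged genes. Genes of a list can vary together and some lists share members, so neither is a chance count for these lists.

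Other lists at 8 hpf lay inside that range and held single 2-fold genes. The stress list had a median of 0.01 over 32 genes (percentile 70.8), with sqstm1, the heat shock gene hsp70l at -2.35 and the heme oxygenase hmox1a at -1.24 2-fold lower. Cholesterol and lipid genes had a median of -0.12 (percentile 14), with dhcr7 the 1 member of 20 that was 2-fold lower. In the steroid and pituitary list, with a median of 0.25 (percentile 95.8), the medians of cyp11a1.1 and cyp17a1, at 1.18, were 2-fold higher, but the 3 spots of cyp17a1 ran from 0.26 to 2.14 and the brightest of cyp11a1.1 stood at -0.46. Enveloping layer and epidermis genes had a median of -0.13 (percentile 8.67), with icn at -2.11 and the keratin krt91 at -1.25 2-fold lower. Mesendoderm and axis genes had a median of 0.09 (percentile 93.4), with wnt5b at 1.22 and the nodal ligand ndr1 at -1.19. Pluripotency and early zygotic genes had a median of 0.15 (percentile 94.5), with sox19b 2.46-fold higher. Neural and glial genes had a median of 0.12 (percentile 94.3), with ascl1b at 1.36, neurod6b at 1.05 and ascl1a at -1.07. The myeloid list, at -0.10 (percentile 25), held nccrp1, 4.61-fold higher, and mmp9 at -1.21. The clock list, at 0.01 (percentile 67.6), held cry5 at 1.62.

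The remaining medians at 8 hpf were 0.02 for skeletal muscle (percentile 68.8; myl10 at 1.03), -0.02 for erythroid genes (62.2; hbae3 at -1.09), 0.05 for vascular endothelium (64.8), 0.01 for lateral line and inner ear (59.6; s100t at -1.41, cldnb at -1.24 and oc90 at 1.15), and -0.27 for lens and retina (4.56). Pigment cell genes stood at -0.08 (percentile 76.6), liver, pancreas and gut genes at -0.14 (31.3; fgb at -1.39 and ela2l at -1.03), and cartilage, bone and matrix genes at -0.02 (51.9). Notochord and somite genes stood at 0.09 (percentile 88.9; ntd5 at -1.40), hatching gland genes at -0.03 (44), cell cycle genes at -0.06 (30.3) and nuclear receptors other than the estrogen receptors at 0.06 (85). In the heart muscle list, 2 genes were measured, hand2 at 0.66 and gata4 at 0.44. Many members of the tissue lists were not measured at this gastrula stage: of genes on the array, 11 of 31 for lens and retina and 8 of 19 for erythroid were. These medians thus describe the measured transcripts and not the state of a tissue, and fgb changed sign without a filter on dim spots.

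In 1 channel only, ccdc137 was at least 25.3-fold, amdhd2 at least 5.69-fold, anxa1c at least 5.46-fold and islr2 at least 5.20-fold higher at 8 hpf, with the control not above background. In the other direction, supt3h was at least 3.92-fold, trim25 at least 3.10-fold, tmem176l.2 at least 2.73-fold and syt10 at least 2.43-fold lower. Measured in Cy5 only were 4873 genes and transcripts, 80 with a bound of 2-fold, against 513 and 20 in Cy3 only. The detection limit was higher in Cy3, so the larger number on the Cy5 side is not read as an effect.

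At 48 hpf, the lists for lens and retina, neural and glial, myeloid and inflammatory, liver, pancreas and gut, cholesterol and lipid, and erythroid genes were lower in MO2-ers2a embryos than other genes of like brightness. The lists for skeletal muscle, notochord and somite, and pluripotency and early zygotic genes were higher. Among the highest named genes were isca1 at 3.80, the galectin lgals1l1 at 3.73, akap17a at 2.77 and 2 genes of muscle, tcap (titin cap) at 2.65 and the actin actc2 at 2.37. The others of the 12 highest were kiaa0895l at 2.59, prrg1 at 2.43, med28 (4.93-fold), cyclin G1 (ccng1) at 2.24 (3 spots, 2.23 to 2.26), lgals3b at 2.16, popdc3 at 2.01 and the Wnt pathway agonist rspo1 at 1.96. The lowest named genes included crx at -2.41 and six7 at -2.06, transcription factors of photoreceptors, vsx1 at -1.96, of retinal bipolar cells, the opsin opn6a at -1.91 and retinoschisin (rs1a) at -1.70. The others were mfap4.3 at -2.49 and mfap4.1 at -1.94, the glucocorticoid-induced fkbp5 at -2.12 (2 spots, -2.69 and -1.56), sat1a.1 at -1.92, tmx3a at -1.85, the troponin tnni1b at -1.72 and neurod6b at -1.70. Of the 24 highest and lowest named genes, 21 at 8 hpf and 20 at 48 hpf rest on 1 spot, and the authors' fold was more than 1.5 times larger for 15 and 11 of them.

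Fewer genes passed 2-fold at 48 hpf than at 8 hpf: 212 higher and 208 lower, of which 128 and 94 had an assigned symbol, with 20 and 16 at 4-fold. Of 68 such genes with 2 or more spots, 66 (97.1%) had all spots on the same side of 0 and 43 had all spots at 2-fold or more. The share of measured genes and transcripts past 2-fold was 2.53%, against 4.57% at 8 hpf. The pooled SD between spots was also smaller, 0.24 against 0.32, so these counts do not compare the size of an effect between the times. The authors' log ratios gave 489 higher and 783 lower, spike-in scaling 275 and 140, centring on measured spots without loess 278 and 434, and centring on all spots 1254 and 84.

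**Figure D1:**
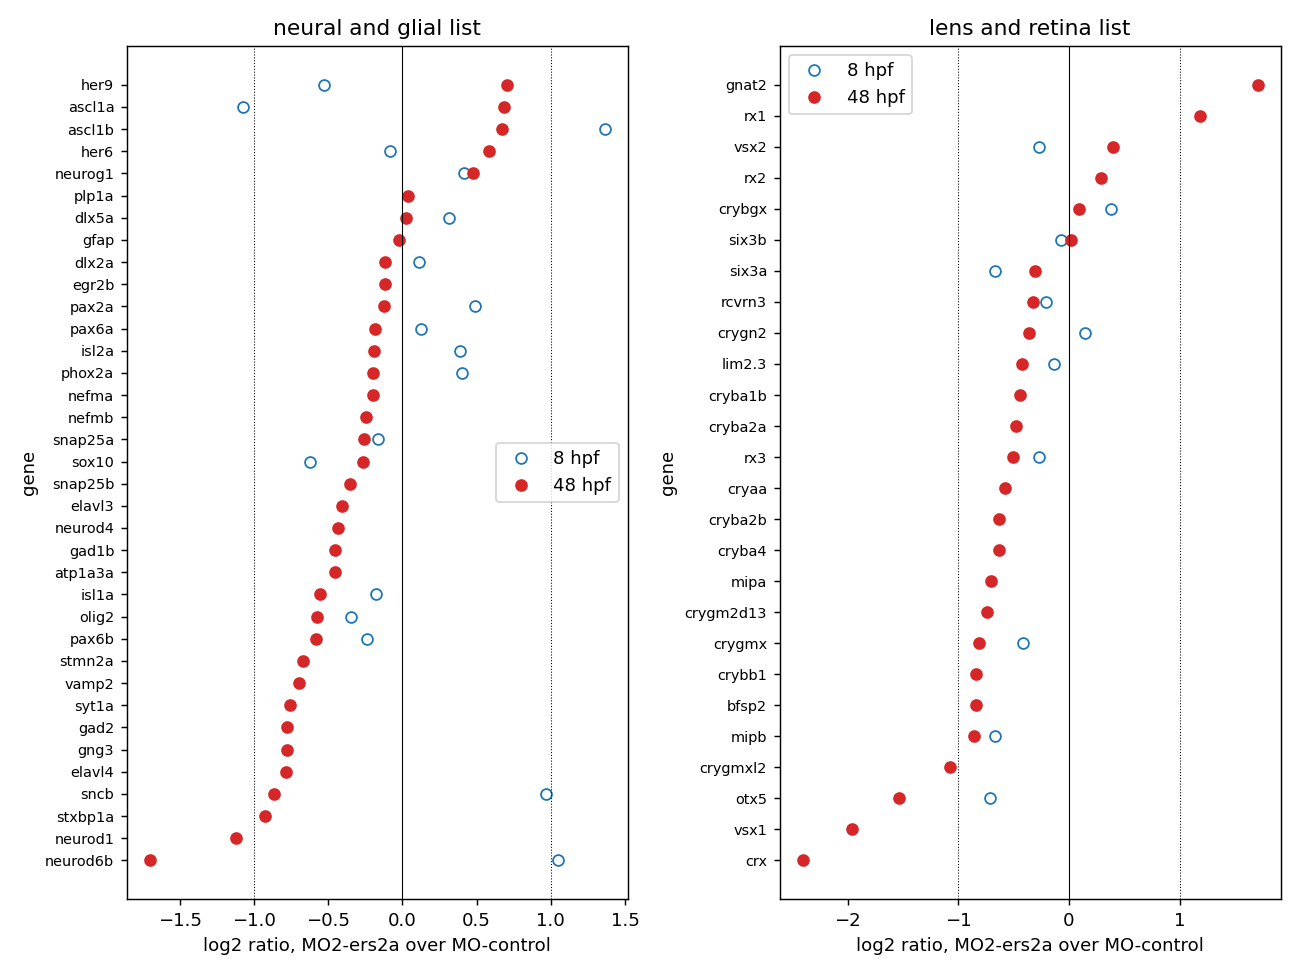
Log2 ratios of MO2-ers2a over MO-control (horizontal axis) for each gene of the neural and glial list and the lens and retina list measured at 48 hpf (vertical axis), with open circles for 8 hpf, filled circles for 48 hpf and dotted lines at 2-fold. The neural and glial list had medians of 0.12 over 18 genes at 8 hpf and -0.31 over 36 at 48 hpf. The lens and retina list had -0.27 over 11 genes and -0.54 over 26. The medians at the 2 times thus cover different sets of genes.

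The lens and retina list had a median of -0.54 at 48 hpf (percentile 0), with 20 of 26 genes below 0. crx, vsx1, otx5 at -1.54 and the lens crystallin crygmxl2 at -1.08 were 2-fold lower, while gnat2, the transducin of cones, at 1.70 and rx1 at 1.19 were 2-fold higher. Neural and glial genes had a median of -0.31 (percentile 0), with 29 of 36 below 0 and neurod6b and neurod1, at -1.12, 2-fold lower; centring on all spots put the median at 0.11. The members went both ways: 7 lay above 0, the highest being her9 at 0.70, ascl1a at 0.68, ascl1b at 0.67, her6 at 0.59 and neurog1 at 0.47. Among those below 0 were stxbp1a at -0.92, sncb at -0.86, elavl4 at -0.78 and gad2 at -0.78. Myeloid and inflammatory genes had a median of -0.45 (percentile 0), with 11 of 14 below 0. Of the 14, mfap4.1, a macrophage marker, was 2-fold lower and nccrp1 at 1.25 2-fold higher; lect2l, which has no assigned current symbol and is left out of the count and the median, stood at -1.49. The authors' values gave this list a median of -0.65. Liver, pancreas and gut genes had a median of -0.26 (percentile 0.02), or 0.19 with centring on all spots, with 16 of 24 below 0 and 8 above; apoa4a at -1.52 and rbp4 at -1.02 were 2-fold lower and the glucagon gene gcga was 2.14-fold higher. Cholesterol and lipid genes had a median of -0.22 (percentile 0.15), or 0.20 with centring on all spots, with apoea at -1.68 2-fold lower. Erythroid genes had a median of -0.22 (percentile 0.8), or 0.26 with centring on all spots, with the globins hbbe2 at -1.25 and hbae5 at -1.02 2-fold lower; without a filter on dim spots the percentile was 2.84.

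Skeletal muscle genes had a median of 0.30 (percentile 99.97), with 23 of 27 above 0 and desma (desmin) at 1.27 2-fold higher (3 spots, 0.78 to 1.45); mef2ca stood at 0.93 and casq1a, the lowest, at -0.19. Pluripotency and early zygotic genes had a median of 0.33 (percentile 99.8), with vox at 1.70, sox19b at 1.25 and her3 at 1.01 2-fold higher of 15. Notochord and somite genes had a median of 0.32 (percentile 99.6), with 13 of 15 above 0 and notch1a at 1.29 2-fold higher. The members below 0 were tbx6 at -0.38 and ripply1 at -0.28, and her1, her7, mespaa and mespba were not measured at 48 hpf. In all, 9 of the 26 lists with a percentile lay outside the middle 95% at 48 hpf. If genes varied independently, 1.3 would be expected, or 2.08 at the 8% found for lists of unchanged genes in the simulation. As at 8 hpf, neither is a chance count for lists whose genes can vary together.

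The other lists at 48 hpf lay inside that range. The hox genes had a median of 0.02 (percentile 43.9; 41 measured), interferon genes -0.18 (18.5), ribosomal proteins 0.06 (89.5; rpl36 at 1.63), and maternal transcripts 0.01 (64.6; nanos3 at 1.16). The stress list stood at -0.08 (percentile 5.8), with fosab at 1.45 (lowest of 4 spots, 0.77), hspb11 at 1.18 and hmox1a at -1.36. Heart muscle genes stood at 0.08 (percentile 63), with tnni1b 2-fold lower, and clock genes at 0.07 (73.6), with nr1d2a at -1.65. Cell cycle genes had a median of 0.00 (percentile 45.3), with gmnn at 1.08. Medians of lists without a 2-fold member were 0.12 for mesendoderm and axis genes (percentile 93.5), 0.19 for enveloping layer and epidermis (96), -0.09 for vascular endothelium (12.2) and -0.15 for lateral line and inner ear (3.02). They were 0.06 for pigment cells (percentile 62), -0.04 for cartilage, bone and matrix (25.8), -0.19 for hatching gland (5.83), -0.07 for steroid and pituitary genes (16.9) and -0.12 for other nuclear receptors (7).

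**Figure D2:**
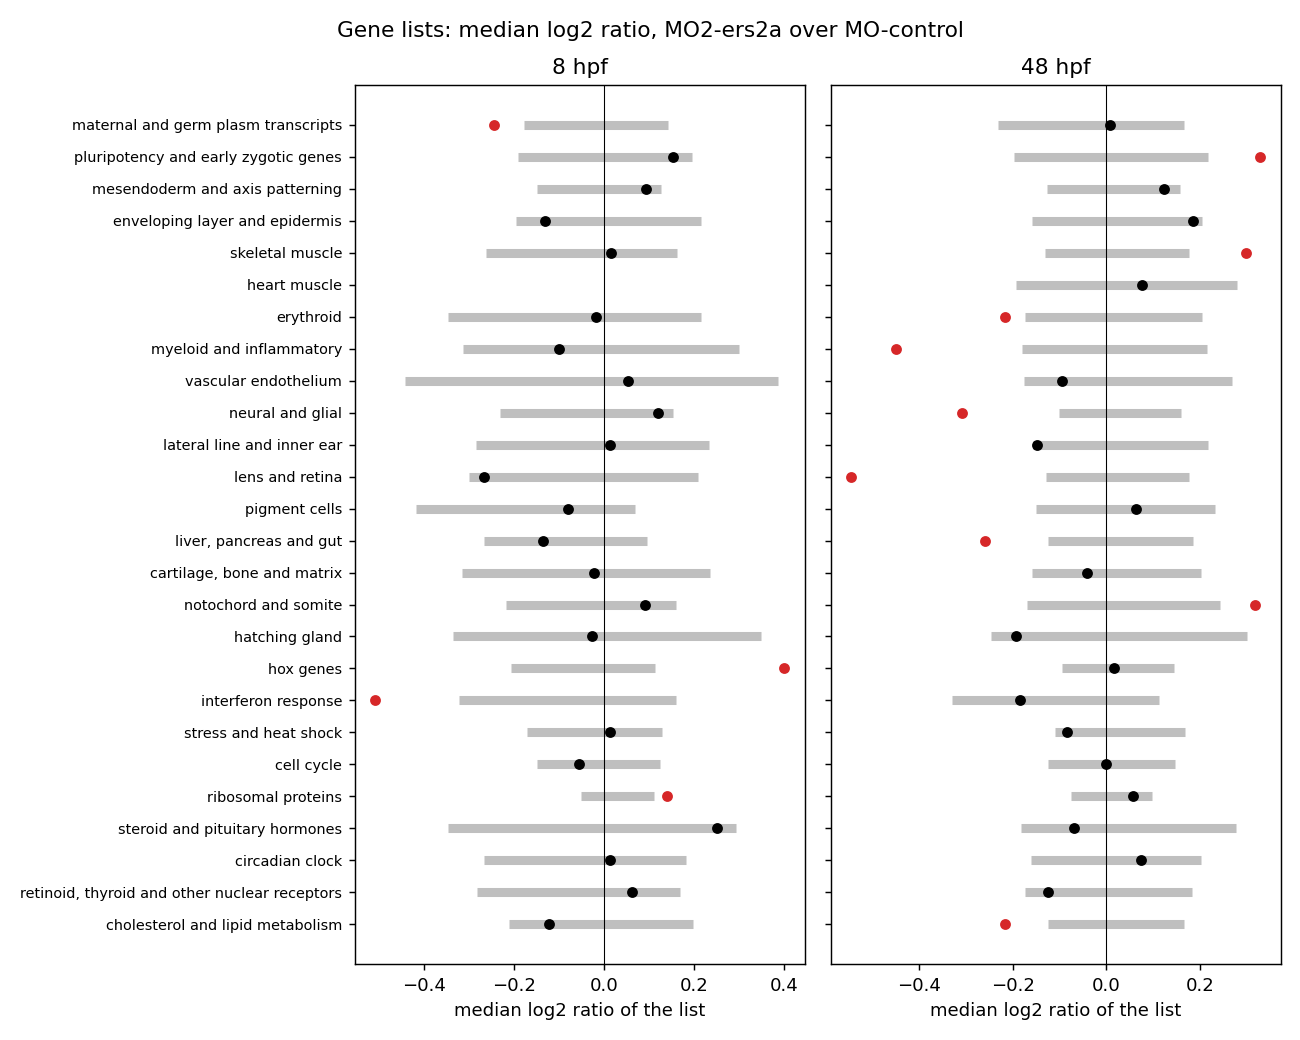
Median log2 ratio of MO2-ers2a over MO-control (horizontal axis) of each gene list (vertical axis) at 8 and 48 hpf, relative to other genes, as points; grey bars span the middle 95% of 10000 random lists matched on intensity, and red points lie outside them. Outside lay 4 lists at 8 hpf and 9 at 48 hpf, with the lens and retina list at -0.54 the lowest at 48 hpf.

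In 1 channel only at 48 hpf, ccdc137 was at least 5.11-fold, pth1a, a parathyroid hormone gene, at least 4.93-fold, amdhd2 at least 4.52-fold and arfgap1 at least 4.20-fold higher. gtf2a2 was at least 3.80-fold, xylb at least 2.75-fold, fam83c at least 2.70-fold and soat2 at least 2.03-fold lower. At this time 4075 genes and transcripts were measured in Cy5 only, 30 with a bound of 2-fold, against 407 and 15 in Cy3 only.

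Most genes that were 2-fold higher or lower at 1 time did not reach 2-fold at the other. Over 13179 genes measured on both arrays, the log2 ratios at 8 and 48 hpf had a Pearson r of 0.240 and a Spearman rho of 0.209 across genes, which are not independent replicates, and a covariance of 0.0451. Among these, 36 were 2-fold higher at both times, where independent lists would share 3.95, and 18 were 2-fold lower at both, against 2.45. The arrays share their dye orientation, so part of this overlap can come from dye bias. Higher at both times were isca1 (4.03 and 3.80), prrg1 (2.24 and 2.43), med28 (4.38-fold and 4.93-fold), rpl36 (2.05 and 1.63), id1, an inhibitor of differentiation factors (4.94-fold and 2.86-fold), and sdhaf2 (1.43 and 1.92). Lower at both were faima (-2.09 and -1.53), hmox1a (-1.24 and -1.36), phc2b (-1.25 and -1.13), nr2e3, a nuclear receptor of photoreceptors (-1.12 and -1.45), nr2c2 (-1.17 and -1.11) and twf1b (-1.47 and -1.09).

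The ratio of MO2-ers2a over MO-control was at least 4-fold larger at 48 than at 8 hpf for 39 genes and transcripts. It was at least 4-fold smaller for 37, which made 76 in all. The authors' values gave 285. Among genes with an assigned symbol, tgm2b moved most on the log2 scale, from -5.30 to 0.67. Next upward came quob (-3.87 to 0.43), b2m (-2.97 to 0.92), s100a10b (-3.52 to -0.01), nap1l4a (-2.83 to 0.54) and ggact.2 (-4.35 to -1.06). In the other direction were gnmt (3.74 to 0.23), tnfaip2a (3.01 to -0.11), cyp11a1.1 (2.41 to -0.65), tspan34b (2.74 to -0.12), ddit4 (2.72 to -0.09) and cfap100 (3.07 to 0.31). For cyp11a1.1 the brightest of 3 spots at 8 hpf was at -0.46, which leaves no 4-fold difference from its 1 spot at 48 hpf.

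**Figure D3:**
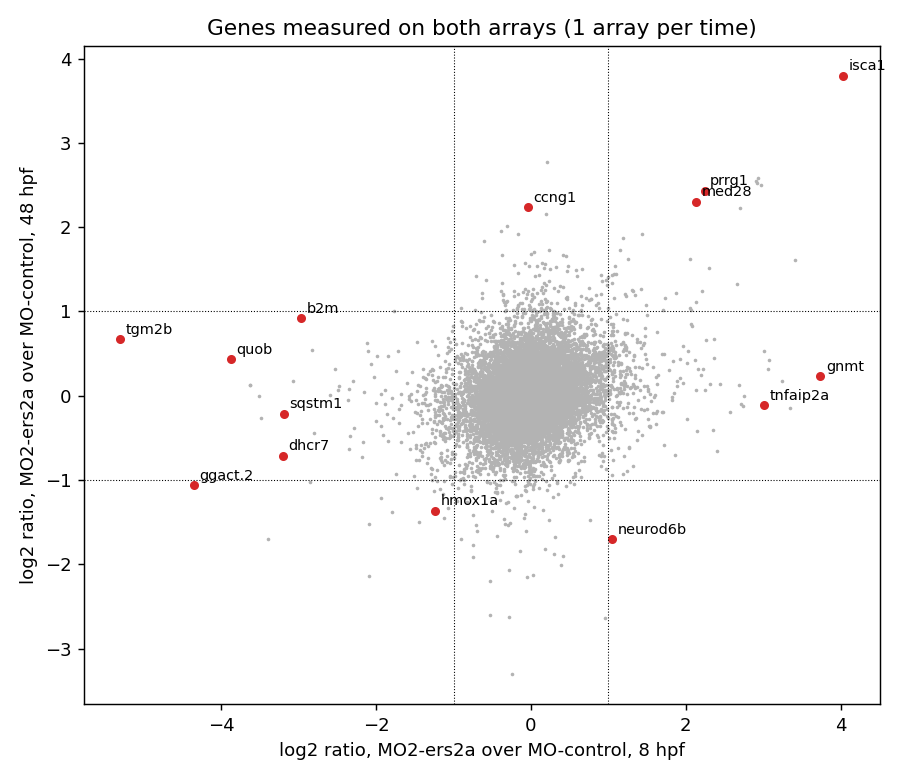
Log2 ratio of MO2-ers2a over MO-control at 8 hpf (horizontal axis) and 48 hpf (vertical axis) for 13179 genes and transcripts measured on both arrays, with dotted lines at 2-fold and some named genes in red. isca1 stood at 4.03 and 3.80, tgm2b at -5.30 and 0.67, and ccng1 at -0.04 and 2.24.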

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

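Among genes measured on both arrays, 1 was 2-fold higher at 8 hpf and 2-fold lower at 48 hpf, and 1 was 2-fold lower at 8 hpf and 2-fold higher at 48 hpf. The first was neurod6b, a neuronal transcription factor gene, at 1.05 and -1.70. The second was a transcript without an assigned symbol (TC343915 in the array design), at -1.77 and, just past the 2-fold limit, higher at 48 hpf, named after its values were seen. They stand out because the direction differs between the times. Each rests on 1 spot per array, independent lists would share 2.53 and 3.82 genes in these directions, and the difference was not tested.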

How the results depend on the processing

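Spike-in scaling and centring on measured spots were chosen after seeing the data. Agilent's processed signals, its spot-level p-value and a slide block were planned and not run, the first pair because only medians were used and the last because each time had 1 array. For the values below the cause was not tested, except that other fold sizes and brighter spots alone admit more or fewer genes by construction. Counts of 2-fold genes, given as higher and lower at 8 hpf, then higher and lower at 48 hpf, were 705, 1030, 489 and 783 with the authors' log ratios; 2490, 96, 1254 and 84 with centring on all spots; 1137, 1234, 940 and 1141 at 1.5-fold; and 99, 71, 41 and 42 at 3-fold. Brighter spots alone gave 208, 176 and, for lower at 48 hpf, 112. Spike-in scaling gave 234 and 551 at 8 hpf, and centring on measured spots without loess gave 633 lower at 8 hpf and 434 lower at 48 hpf. Genes differing between times numbered 285 with the authors' values, 128 without a filter on dim spots, 26 among brighter spots, 504 at the square of 1.5-fold and 13 at the square of 3-fold. The correlation between times was 0.331 with either centring without loess, 0.253 with spots measured in at least 1 channel, 0.230 without a filter and 0.276 among brighter spots. Among named genes that were 2-fold, a reversed sign was found for cyp11a1.1 (-0.46) and rpl36 (-0.0051) at 8 hpf with the brightest spot per gene, and for fgb at 8 hpf (0.21) without a filter. Of values of named genes within 2-fold, the sign changed in 16 of 289 with the authors' values and in 79 of 290 with centring on all spots. Of 13 lists outside the middle 95%, 10 stayed outside on the same side under each of up to 10 alternatives that gave them a value; the exceptions were maternal and ribosomal genes at 8 hpf and erythroid genes at 48 hpf. Of 506 list values under the alternatives, 4 came inside the range and 21 moved outside it. Of 3876 values of named genes, 59 lost 2-fold and 122 gained it. Signal over background limits the arrays: fewer spots were measured in Cy3 (20052 and 21463) than in Cy5 (25523 and 26290).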

Other observations

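The comparison with muscle genes was chosen after the results were seen. The tests on stage and on dye bias were fixed before their values were computed. The reading of the stage tests and of the hox dye bias test was changed after their values were seen. The standard errors and bootstrap SDs below treat genes as independent and hold no error between arrays or embryos.

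Spots of one gene often differed among genes picked because at least 1 spot was 2-fold the same way at both times. Picking genes by any such spot favours differences between spots, so the shares below do not describe genes called by their median. Of 24 genes with 2 or more spots on both arrays and at least 1 spot 2-fold the same way on both, 9 (37.5%, exact 95% interval 18.8 to 59.4%) had all spots 2-fold that way. The share was 8 of 18 for higher and 1 of 6 for lower spots. Of genes with a spot 2-fold on only 1 array, which can include some of the 24, all spots passed in 20.1% of 149 at 8 hpf and 25.3% of 91 at 48 hpf. rpl36 shows the pattern, with spots at -0.01 and 4.11 at 8 hpf and 0.30 and 2.95 at 48 hpf, whereas both sdhaf2 spots passed at both times.

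As lists, neural and glial genes and lens and retina genes had lower medians, and skeletal muscle genes a higher one, at 48 hpf, with members of each list going both ways. The pattern is thus not one of all tissues lowered alike. Relative to other genes, the skeletal muscle list had a median of 0.30, against -0.31 for the neural and glial list and -0.54 for the lens and retina list. The muscle median is part of the pattern, so it is no separate test of a delay. A delay of the whole embryo could also show across all genes: those at least 4-fold brighter at 48 than at 8 hpf had a median log2 ratio 0.15 below those at least 4-fold dimmer (difference -0.15, bootstrap SD 0.02; 1934 and 769 genes). The 8 hpf array gave -0.18, so a shared bias along this axis, or embryos less advanced at both times, cannot be told apart from a delay at 48 hpf. Dye bias in the neural, lens and retina genes also stays open. In the 29 members measured on both arrays, the mean of 48 minus 8 hpf was -0.23, with a standard error over genes of 0.15.

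Hox genes were higher and maternal transcripts lower at 8 hpf. In 28 hox genes the mean of 48 minus 8 hpf was -0.28 with a standard error over genes of 0.09. By the bound set beforehand this counts against dye bias as the whole cause. That bound took no account of each array's zero. It also took no account of the hox list being picked for its high values at 8 hpf, which alone favours a fall from 8 to 48 hpf. The mean of the 10 spike-in probe medians also moved, from 0.16 at 8 hpf to -0.09 at 48 hpf. Dye bias in the hox genes thus stays open. For the 13 maternal transcripts measured on both arrays the mean of 48 minus 8 hpf was 0.25, with a standard error over genes of 0.18. This also leaves dye bias open. A later stage of MO2-ers2a embryos than controls also stays open: genes brighter at 48 hpf had a median log2 ratio at 8 hpf that differed by -0.18 from that of dimmer genes (bootstrap SD 0.03), and the bound set beforehand, 0 or below, took no account of a bias shared by the arrays, which the -0.15 at 48 hpf allows. The morpholino itself, as the design's biological difference, remains untested without replicates.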
